A study of Drosophila melanogaster with 3 samples.

How the data were processed

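The samples were 3 biological replicates of whole adult female flies of 1 transgenic line, each an immunoprecipitation of tj-eGFP with an anti-GFP antibody. The deposited values are lists of called peaks, on builds dm3 and dm6, 5 on each: 1 per replicate, 1 from the pooled replicates, and the IDR list. Per the files' accompanying descriptions, the replicate lists were derived from each replicate's alignments and a control alignment, are relaxed lists that include background as input for an irreproducible discovery rate (IDR) analysis, and the IDR list was derived from the replicate lists and the pooled list. The aligner, peak caller, versions and IDR threshold are not given in the sources used here. The deposited signal of a peak is the caller's enrichment value, with no stated unit, and it was used to rank peaks within a list. The deposited q-value of a peak is on the −log10 scale and ran from 0.13 to 4.41, too narrow a range to rank by, so it was not used. Read depth is unknown, and no interval that needs it is given. Wilson and exact intervals over peaks or genes cover counting error only. All per-sample value columns of the lists were mapped to samples.

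Each replicate's file was assigned by its recorded sample and replicate number. Analyses used dm6. The dm3 lists served for counts and concordance, and no coordinates were converted. Sequence came from the NCBI Release 6 assembly, genes and TSSs from Ensembl release 115 (BDGP 6.54) with transposable elements left out, and older symbols and the position of flam from NCBI's gene table. The analysis was limited to 2L, 2R, 3L, 3R, 4 and X. No IDR summit lay elsewhere on dm6. Summits of different lists matched within 200 bp. Concordance used the 10688 strongest peaks of each replicate, the length of the IDR list, and 100 shuffles. For relative signal, the strongest replicate summit within 200 bp of an IDR summit was divided by that replicate's median, so neighbouring summits could share a value.

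A summit was classed as promoter within 500 bp of any TSS, then as 5' UTR, coding sequence, 3' UTR, non-coding exon, intron or intergenic, and compared with 1000 uniform shuffles within chromosomes. Density on X and 4 was tested with exact binomial tests. Genes were called bound with a summit within 1000 bp of a TSS. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 20 lists. Of 340 symbols written in the lists, 323 matched by symbol, 12 by an older symbol, 1 by letter case (a match added after the data were seen), and 4 did not match 1 gene and were not analysed here. Ribosomal protein and histone genes, 207 in all, were taken by name pattern. Motif shares within 100 bp of the summit were compared with the mean of 2 windows 1000 bp away. Medians were compared by permutation, with 100000 resamples and 20000 in the alternatives. The rule for named genes was tj, piwi, fs(1)Yb, Fas3, shg, Fas2, CadN and flam; the nearest coding TSS of the 20 strongest IDR peaks; up to 4 members per list with the strongest promoter peak and unbound members where there were 5 or fewer; and the 10 genes with most summits. Lists, tests, named-gene rule and the other settings below were fixed before the data were examined.

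The planned sign test for motifs proved unsuitable. A rare motif falls in 1 of 3 windows, so without enrichment a peak more often has less than the mean of its flanks than more. On simulated sets of 3000 peaks with no implanted site, it gave p under 0.05 in 99.5% of sets. An exact window exchange test, in which each of a peak's 3 windows is equally likely to be the summit, did so in 3.5% and was added after the data were seen. Both are given. A sign test passed toward the summit is conservative, and one passed toward the flanks is not interpretable.

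The other statistics were also tested on simulated data. For concordance, 79.2% of 10688 summits were made shared and 79.7% were found. For gene lists, run on 13945 genes, 200 genes bound at 63.5% gave a Fisher p of 2.10e-15, and 3.5% of random lists of 20 passed 0.05. With an implant of the core the expected and recovered share were both 8.26%. For positions, 39.7% was expected at promoters and 39.8% found. Permutations of medians passed 0.05 in 5% of sets with no difference.

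Alternatives used the strongest 5344 IDR peaks, peaks matched in all 3 replicates (8177), the same number of strongest peaks from the pooled list, or peaks matched in both replicates after leaving 1 out (8757 to 8892), and other distances, windows and mismatch limits. Using 1 summit per region (9571) and the exchange test were added after the data were seen. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. Signal tracks were not used here, and no immunoprecipitation from untagged flies was analysed here.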

Results

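Chromatin immunoprecipitation with sequencing was carried out on whole adult female Drosophila melanogaster from a transgenic line that makes Traffic jam (tj) fused to eGFP at its C terminus. Traffic jam is a large Maf transcription factor of the basic leucine zipper (bZIP) class, known from the somatic cells of the gonad and from other tissues. The fusion protein was recovered with an antibody against GFP from chromatin sonicated to fragments of 200 to 800 bp. The samples form 1 group of 3 biological replicates, and no second group was compared. Values are positions and signal values of called peaks. Read numbers were not among the values analysed here, so the sequencing depth of each replicate is unknown. Positions are given in dm6, the Release 6 genome.

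Each replicate list and the list made from the pooled replicates held 30000 peaks, and the reproducible (IDR) list held 10688 summits in 9571 distinct regions with a median width of 504 bp. Signal values in the IDR list ran from 215.6 to 12004 with a median of 454.5, in the peak caller's own units. On the older build, dm3, the corresponding list held 10318 peaks. Median signal at IDR peaks differed between replicates, at 113.6 in replicate 1, 242.1 in replicate 2 and 160.6 in replicate 3, so values below are relative to each replicate's median. A relative signal of 1 is that median, over the 10265 IDR peaks with a summit within 200 bp in all 3 replicate lists.

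The first question was whether the replicates found the same sites. Of the 10688 strongest summits of a replicate, 84.5% lay within 200 bp of one of the 10688 strongest summits of another, as the mean of the 6 ordered pairs, which ranged from 82.1% to 85.9%. Summits shuffled within chromosomes gave 2.92%. Of the IDR peaks, 8177 (76.5%) were matched among the 10688 strongest summits of all 3 replicates, 1964 in 2, 527 in 1 and 20 in none. The IDR list was itself derived from the replicate and pooled lists, so its match to the replicates is partly built in. Across the 10265 IDR peaks with a summit in all 3 replicate lists, which are not independent replicates, Spearman's rho of the signal was 0.791 for replicates 1 and 2, 0.785 for 1 and 3, and 0.789 for 2 and 3. The median SD of the log2 relative signal over the 3 replicates was 0.30. These shares depended on the distance counted as a match and were 62.7% and 51.7% at 50 bp.

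The strongest sites lay at genes of varied function. Ordered by the signal of the pooled replicates, the first was at the promoter of Glyp, which encodes glycogen phosphorylase (2L, 2130125 to 2131059; relative signal 23.5 ± 2.53, SD, n = 3), followed by the promoter of ttk, which encodes the transcriptional repressor Tramtrack (3R, 31712799 to 31714226; 23.5 ± 4.78). An intronic region of CG32772 (X, 4908846 to 4911102) held 2 of the 20 strongest summits, the stronger at 21.5 ± 4.19. An intron of Smr, which encodes a nuclear receptor corepressor, held the next (X, 12721122 to 12723031; 17.1 ± 2.66), with CG15725 as the nearest coding transcription start site (TSS). Promoter summits among the 20 also fell at CG4452 (15.2 ± 1.68), at zip, the non-muscle myosin heavy chain gene (14.5 ± 2.46), at the translational repressor gene brat (12.9 ± 1.96), at the tropomyosin gene Tm1 (12.3 ± 3.87), at the yolk protein gene Yp3 (11.4 ± 1.08) and at CG17734 (11.3 ± 1.57). Intronic summits fell in CG11050 (14.3 ± 1.00), drongo (13.4 ± 1.77), aop, which encodes an ETS repressor (13.1 ± 1.05), SNF4Agamma, a subunit of AMP-activated kinase (12.6 ± 1.36), CG30089 (11.5 ± 1.67), the zinc finger gene shn (11.5 ± 2.14) and Vha100-2, a proton pump subunit (11.1 ± 1.59). All 20 summits were among the strongest 10688 in each of the 3 replicates.

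The tj gene itself lay in a cluster of sites. Downstream of tj (2L, 19464267 to 19467758, plus strand), 1 intergenic region from 19471990 to 19474689 held 3 summits, of which 2 were among the 20 strongest of the list. Their relative signals were 13.1 ± 0.94, 12.8 ± 1.32 and 10.6 ± 1.36 (SD, n = 3), at 9330, 8189 and 9537 bp from the tj TSS. The strongest summit at the tj promoter (2L, 19463799 to 19464511) had a relative signal of 2.38 ± 0.82. In all, 13 summits lay within 10 kb of the gene. The line is described as transgenic, and whether it carries extra copies of tj is not given in the sources used here.

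**Figure D1:**
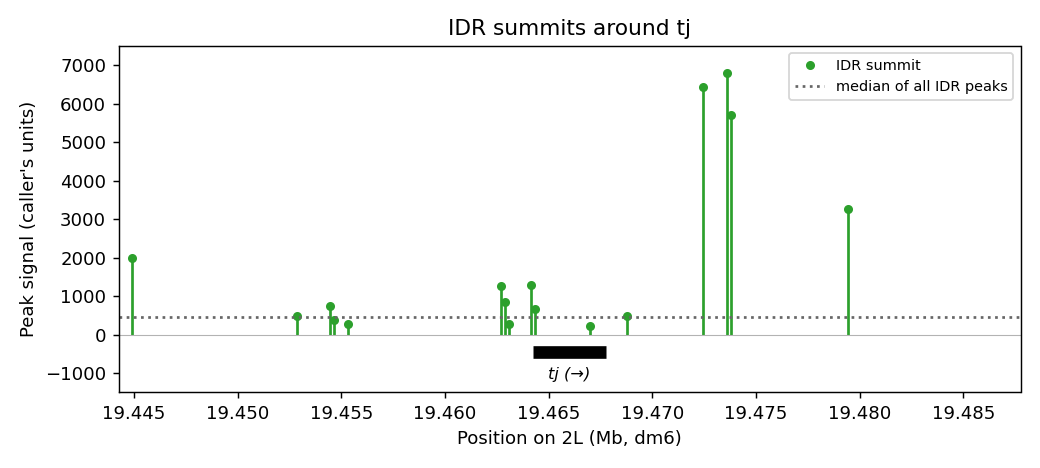
IDR summits within 20 kb of tj on 2L (dm6), with position in Mb on the horizontal axis and the signal value of the pooled replicates on the vertical axis. Each stem is 1 summit, the black bar is the gene and the dotted line is the median of all IDR peaks (454.5); the 3 tallest stems are the summits of the region from 19471990 to 19474689.

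The named genes of the gonad soma were bound to differing degrees. Of the 8 genes and loci named in advance, those of the piRNA pathway were led by the 5' end of flam (X, 21632042 to 21632704; 7.29 ± 0.66), the start of a somatic piRNA cluster that the NCBI annotation places at X, 21631891 to 21790731. The promoter of fs(1)Yb, a somatic piRNA biogenesis factor, had a weaker site with the Maf core sequence TGCTGAC within 100 bp (X, 2720551 to 2720893; 1.77 ± 0.22). The promoter of piwi, the Argonaute gene of the pathway, had 1 site whose signal varied between replicates (2L, 10986855 to 10987213; 1.36 ± 0.76). Among adhesion genes, Fas3 held 13 summits between its start and end, the strongest intronic (2L, 18331975 to 18332697; 2.60 ± 0.48), and Fas2 held 9, the strongest also intronic (X, 4186652 to 4187383; 3.55 ± 0.53). The promoter of shg, the E-cadherin gene, had a summit near the median (2R, 21056829 to 21057332; 0.96 ± 0.21), and an intergenic summit beyond its 3' end was stronger (2R, 21045666 to 21046559; 5.31 ± 0.86). CadN, the N-cadherin gene, had 3 intronic summits, the strongest at 0.72 ± 0.16, and no promoter summit. Of the summits whose signal is given in this paragraph, only that of fs(1)Yb held the core TGCTGAC. No IDR summit within 20 kb of tj held it.

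Binding was concentrated at promoters. Of the IDR summits, 5163 (48.3%, 95% Wilson interval 47.4 to 49.3%) lay within 500 bp of a TSS, against 13.6% of summits shuffled within their chromosome, a 3.56-fold excess. Introns held 39.5% of summits against 39.6% by shuffling (permutation p = 0.407). Coding sequence held 0.936% against 13.7%, 3' UTRs 1.11% against 4.47%, and intergenic sequence 8.30% against 27.1%. The 5' UTRs beyond the promoter window held 1.24% against 0.783%, and exons of non-coding genes 0.636% against 0.812% (permutation p = 0.024). For the classes without a p here, one-sided permutation p was 0.001, the smallest that 1000 shuffles can give. Uniform shuffling does not account for differences in mappability or chromatin accessibility.

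**Figure D2:**
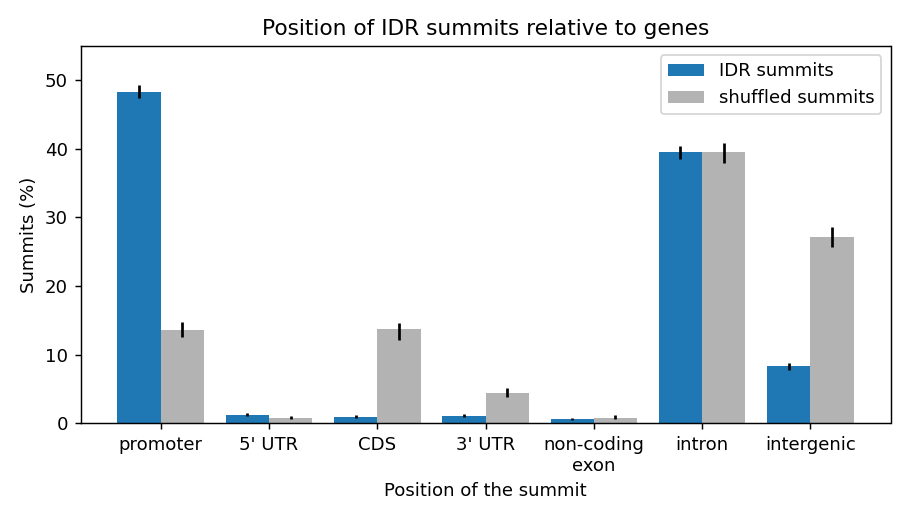
Share of IDR summits (blue) and of shuffled summits (grey) in each class of position, as percent of summits. Error bars are the 95% Wilson interval for IDR summits and the range of 1000 shuffles for shuffled ones; promoters held 48.3% against 13.6%, and coding sequence 0.936% against 13.7%.

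The X chromosome carried more sites for its length and chromosome 4 fewer. Summits numbered 91.7 per Mb on X and 26.7 per Mb on 4, against 79.8 per Mb over the 6 arms. The density on X was 1.15 times that expected from length (2160 summits, two-sided exact binomial p = 2.49e-12), and that on 4 was 0.334 times (36 summits, p = 1.60e-15). On dm3, 20.4% of peaks lay on X, against 20.2% on dm6. These tests treat summits as independent, although some regions held several.

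Within 1000 bp of a TSS, 5073 of 13945 protein-coding genes (36.4%) had a summit, and 3000 had one between gene start and end. Of 20 gene lists, 9 differed from the other coding genes after Benjamini-Hochberg adjustment of two-sided Fisher's exact tests, 6 above and 3 below. The window can assign 1 summit to neighbouring genes that share a promoter region, and 12 genes were in more than 1 list. Where a list is tested without a replicate, IDR peaks were kept if matched in both other replicates (8757 to 8892 peaks). The IDR list itself was still made from all 3 replicates, so this is a stricter peak filter and not a new peak call. Below, "matched" p-values compare a list with 10000 random lists of the same gene length decile and number of TSSs, and are adjusted over the 20 lists. Lists were not matched on expression or promoter accessibility. Whether these account for any difference between lists was not tested.

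Ribosomal protein genes were the list most often bound among those tested with more than 20 members. A promoter summit was present at 78 of 92 (84.8%; adjusted exact p = 2.05e-20, matched 0.00133, the smallest adjusted value obtained). The strongest was at RpS5b, a paralog of RpS5a (3R, 14901471 to 14902386, relative signal 8.19 ± 0.86). That peak held the palindromic Maf site with at most 2 mismatches. RpL23 (4.57 ± 1.04), RpL36 (3.87 ± 0.74) and RpS24 (3.56 ± 0.19) followed. Of the 109 summits at promoters of these genes, 6 (5.5%) held TGCTGAC, against 4.80% of all IDR summits within 500 bp of a TSS.

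Genes of the basement membrane and its integrin receptors were bound at 13 of 14 promoters (adjusted exact p = 8.98e-05, matched 0.0183), with Mmp1, a matrix metalloproteinase gene, the only member without a summit. Examples are Timp, a metalloproteinase inhibitor (5.45 ± 1.62), the integrin gene mys (3.25 ± 0.60), the laminin gene LanB2 (3.20 ± 0.31) and SPARC (2.08 ± 0.07). Genes of bZIP factors, the class of Traffic jam, were bound at 15 of 17 promoters (adjusted exact p = 8.98e-05, matched 0.004), with Atf-2 and gt unbound. The strongest were at Xbp1, a factor of the unfolded protein response (8.28 ± 1.58), cnc (4.87 ± 0.51), vri (3.6 ± 0.76) and CrebB (3.45 ± 0.48).

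Ecdysone genes were bound at 13 of 17 promoters (adjusted exact p = 0.00541), and the call was lost against lists of matched genes (matched p = 0.216). The strongest were at sad, a steroidogenic enzyme (10.0 ± 1.17), Eip74EF (5.17 ± 0.38), br (3.84 ± 0.90) and the receptor gene EcR (3.78 ± 0.39), while Eip78C, Hr38, Hr4 and nvd had none. Genes of cnc and the antioxidant response were bound at 16 of 27 (adjusted exact p = 0.0406, matched 0.0225), led by Keap1 (5.46 ± 0.31), cnc, Cat (3.18 ± 1.07) and Gclc (2.22 ± 0.52). That call did not hold without replicate 1 (adjusted exact p = 0.0708), without replicate 3 (0.0705), in the strongest 5344 peaks (0.0508), at 500 bp (0.137) or over the gene body (0.103). Yolk and fat body genes were bound at 9 of 13 (adjusted exact p = 0.0429, matched 0.455), led by the 3 yolk protein genes Yp3, Yp1 (6.80 ± 0.47) and Yp2 (6.38 ± 0.53), then Desat1 (2.13 ± 0.05), with Apoltp, Fbp1, Fbp2 and apolpp unbound. This call was lost when any replicate was left out (adjusted exact p = 0.0623 to 0.290) and in 9 of 10 other settings in all.

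Of 19 neuronal genes 1 had a promoter summit (adjusted exact p = 0.0108, matched 0.00133), at elav (3.49 ± 0.55), where the summit lay inside the neighbouring gene arg. The neuronal call was lost in the strongest 5344 peaks (odds ratio 0.303, adjusted exact p = 0.235). Of 16 digestive genes 1 was bound, LManII (1.55 ± 0.38; adjusted exact p = 0.0263, matched 0.264), and that call was lost when any replicate was left out (adjusted exact p = 0.0587 to 0.0708) and in 7 of 10 other settings in all. Muscle genes and optic lobe factors were each bound at 4 of 19 (adjusted exact p = 0.259 for both), which lay below matched genes (matched p = 0.0056 and 0.0293). The bound muscle list members were Tm1, Zasp52 (3.37 ± 0.43), flr (0.74 ± 0.18) and Zasp66, which had a summit in the lists of 2 replicates, and the bound optic lobe factors were sim (1.69 ± 0.23), pdm3 (1.56 ± 0.34), eyg (1.59 ± 0.68) and ey (0.73 ± 0.19). Histone genes were bound at 3 of 115 (adjusted exact p = 1.23e-17, matched 0.00133). The bound members were His3.3B (2.72 ± 0.41), His2Av (1.90 ± 0.53, summit inside and nearest to ball) and His4r (0.99 ± 0.16, summit inside and nearest to put), and most other members are near-identical tandem copies, which limits what a list of called peaks can show for them.

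The piRNA lists addressed whether pathway genes used in ovarian somatic cells were bound more often than germline ones. Promoter summits were present at 10 of 15 somatic piRNA genes and 7 of 17 germline piRNA genes, a difference that did not pass the test (odds ratio 2.67, two-sided Fisher's exact p = 0.178). Against the other coding genes, the somatic list had an adjusted p of 0.0550 (matched 0.106) and the germline list 0.802 (matched 1). The somatic list passed when any replicate was left out (adjusted exact p = 0.0292 to 0.0311), when 31.4% to 32.2% of all coding genes were bound, and in 8 of 10 other settings in all (lowest adjusted exact p = 0.00201, over the gene body). With a window of 2000 bp the direct comparison also passed (odds ratio 5, Fisher's exact p = 0.0359). The strongest somatic members were Panx (8.90 ± 1.11), shu (5.61 ± 0.53), nxf2 (5.59 ± 0.66) and the helicase gene armi (5.34 ± 1.25), with Gasz, Hen1, arx, vret and zuc unbound. The strongest germline members were tapas (8.0 ± 1.47), squ (5.61 ± 0.75), whose summit was nearer to a start of grp, spn-E (2.41 ± 0.54) and Boot (1.56 ± 0.43).

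Of the remaining lists, none passed against all other coding genes with the window of 1000 bp and all IDR peaks. Eggshell genes were bound at 11 of 20 (adjusted exact p = 0.137, but 0.00993 at 2000 bp), above matched genes (matched p = 0.0107). Their strongest sites were at the vitelline membrane genes Vm34Ca (6.98 ± 0.23), Vm26Ab (6.96 ± 0.44, nearer to CG13998), Vm26Aa (5.88 ± 0.52) and Vm26Ac (5.16 ± 0.59). Regulators of the gonad soma were bound at 17 of 30 (adjusted exact p = 0.0624; 0.0396 without replicate 2, and past the threshold in 5 of 10 other settings, with 0.00201 over the gene body; matched 1), led by ttk, apt (6.27 ± 1.63), Egfr (4.78 ± 0.84) and br. Adhesion and polarity genes were bound at 13 of 24 (adjusted exact p = 0.126, matched 0.935). They passed at 2000 bp (adjusted exact p = 0.0346) and over the gene body (0.00101), settings that were not matched for gene length. Over the gene body the odds ratio was 4.83, against 2.06 with the window of 1000 bp. They were led by dlg1 (6.23 ± 0.69), crb (3.6 ± 0.15), sdt (2.02 ± 0.28) and aPKC (1.90 ± 0.53, nearer to ckn). EGFR pathway genes were bound at 10 of 16 (adjusted exact p = 0.0624, matched 0.467). That list passed without replicate 3 (adjusted exact p = 0.0312) and over the gene body (0.0208), but not without replicate 1 (0.246) or replicate 2 (0.222). Its strongest members after Egfr were sty (2.86 ± 0.30), aop (2.09 ± 0.59) and kek1 (2.04 ± 0.13). JAK/STAT genes were bound at 7 of 11 (adjusted exact p = 0.140, matched 0.57), and passed with the peaks matched in all 3 replicates (adjusted exact p = 0.0474). They were led by Stat92E (5.52 ± 0.67), Socs36E (3.93 ± 1.09), Ptp61F (1.93 ± 0.40) and dome (1.57 ± 0.40), with et, upd1, upd2 and upd3 unbound. Germline genes were bound at 10 of 17 (adjusted exact p = 0.115, matched 0.935), and passed over the gene body (adjusted exact p = 0.0420). They were led by pum (2.66 ± 0.39), swa (1.80 ± 0.35, inside Marf), Sxl (1.63 ± 0.09) and piwi. Notch pathway genes were bound at 8 of 17 (adjusted exact p = 0.474, matched 0.554), led by neur (2.26 ± 0.16), E(spl)mbeta-HLH (1.83 ± 0.38), kuz (1.45 ± 0.36) and E(spl)m3-HLH (1.32 ± 0.54).

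**Figure D3:**
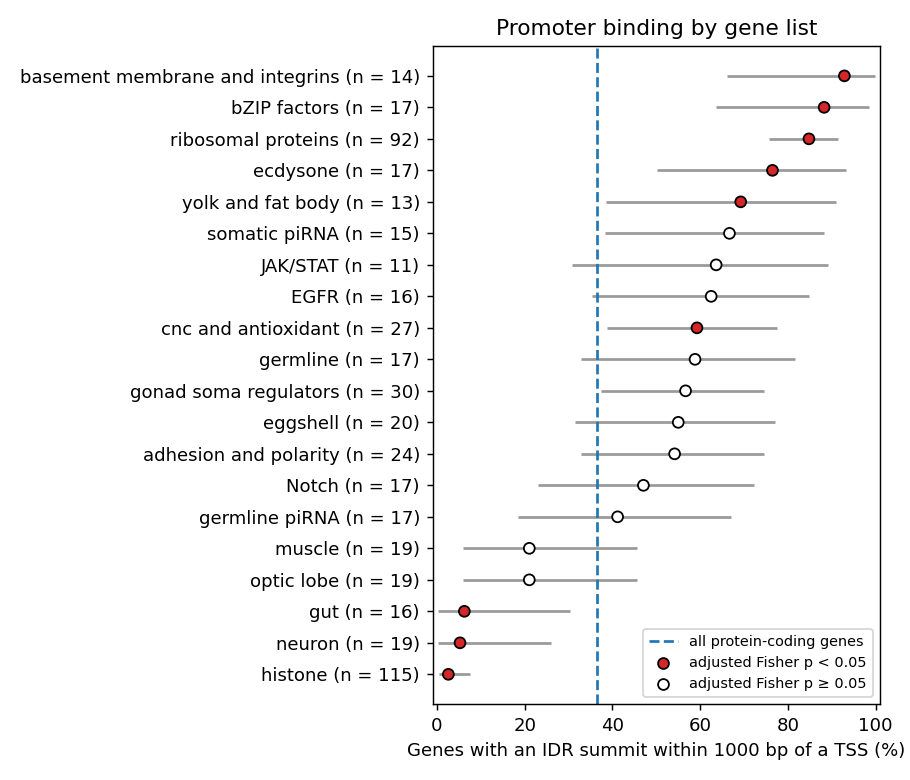
Share of each list's genes with an IDR summit within 1000 bp of a TSS, in percent, with 95% exact binomial intervals. Red points passed the adjusted Fisher's exact test and the dashed line is the share of all protein-coding genes (36.4%); ribosomal protein, bZIP and basement membrane genes lie to its right, and histone, neuronal and digestive genes to its left.

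Several regulatory genes held many sites along their length. The most summits between gene start and end were in sbb (37), bun (32), Eip74EF (31), Eip75B (31), Svil (30), Tlk (28), shn (26), EcR (24), Smr (24) and Pdp1 (23). Of these, Eip74EF, Eip75B and EcR are ecdysone response genes and Pdp1 encodes a bZIP factor. All are long, from 55912 bp for Pdp1 to 121572 bp for Svil, and the density was highest in Eip74EF, at 5.11 summits per 10 kb.

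The Maf recognition sequence was enriched at the summits, although most summits lacked it. Of the 20 strongest summits, 5 held its core within 100 bp. The core TGCTGAC lay within 100 bp of 6.84% of summits, against 2.51% of windows 1000 bp to either side, a ratio of 2.72 (731 peaks with more than their flanks, 495 with less; exact sign test p = 1.67e-11, exact window exchange test p = 1.06e-72). Its ratio ranked 1 of 8192 distinct 7-mers and 1 of 630 with the same base composition. The palindromic site with at most 2 mismatches lay at 2.17% of summits against 0.515% of flanks, a ratio of 4.22 (exact sign test p = 3.77e-11, exact exchange test p = 2.04e-38). The core was nearer the flank level at promoters: 4.80% of promoter peaks held it against 2.67% of their flanks, a ratio of 1.80 with a sign test p of 0.789 and an exchange test p of 1.75e-11. Of the other peaks, 8.74% held it against 2.36% of flanks, a ratio of 3.70. The shares at promoter and other peaks differed (two-sided Fisher's exact p = 5.31e-16).

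Other sequences were also enriched, of which the AP-1 site is the centre of the palindromic Maf site and the antioxidant response element shares TGAC with the core. Of 10 other sequences, only the DNA replication-related element (2.49% of summits against 0.674% of flanks) and core promoter Motif 1 (1.30% against 0.271%) passed the planned sign test toward the summit, with adjusted p of 2.63e-09 and 8.93e-09. The exact exchange test, which was added after the data were seen, called 6 above their flanks: those 2, the GAGA factor site (7.01% against 3.73%), the antioxidant response element (9.16% against 6.1%), the E-box (11.7% against 9.67%) and the AP-1 site (2.70% against 2.18%, adjusted exact p = 0.00560). Below their flanks in that exact test were the sites of Zelda (0.795% against 1.29%, adjusted exact p = 7.96e-05), Scalloped (7.70% against 9.05%, 6.74e-05), Stat92E (5.62% against 6.18%, 0.0480) and GATA factors (2.43% against 2.82%, 0.0480). At promoter peaks the replication-related element was 16.7 times as frequent as at other peaks (4.84% against 0.29%). Motif 1 was 73.3 times as frequent (2.65% against 0.0362% of 5525 other peaks). The ratio for Motif 1 is imprecise, since so few other peaks held it. The E-box lay at 14.1% of promoter peaks and 9.54% of other peaks, the latter no higher than its flank share over all summits. The GAGA factor site differed little (7.09% against 6.93%). The AP-1 site (2.15% against 3.22%) and the antioxidant response element (7.42% against 10.8%) were rarer at promoter peaks.

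Peaks with the core were stronger. The median signal of the 731 peaks with TGCTGAC was 647.9, against 446.1 for the other 9957, a ratio of 1.45 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). With the list divided into 5 equal groups by signal, the core was present in 12.3% of the strongest group (95% Wilson interval 10.9 to 13.7%) and in 6.78%, 5.33%, 5.19% and 4.63% of the following ones, while the flanks stayed between 2.43% and 2.64%. The comparison is across peaks, which are not replicates.

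**Figure D4:**
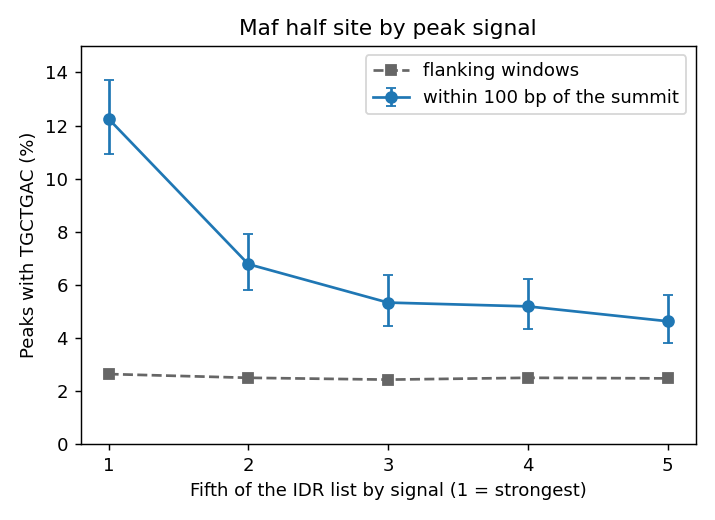
Percent of IDR peaks with TGCTGAC within 100 bp of the summit (points, with 95% Wilson intervals) and in the flanking windows (squares), for 5 equal groups of the list from the strongest signal (1) to the weakest (5). The summit share was 12.3% in the strongest group and 4.63% in the weakest.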

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

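On dm3, 10 IDR peaks lay on heterochromatic or unplaced contigs, which were counted in the whole dm3 lists but not examined by position: 5 on XHet, 4 on 3LHet and 1 on U. The replicate lists on dm3 held 38 to 50 peaks outside the 6 arms, and those on dm6 held 0. No dm3 contig was compared with dm6.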

How the results depend on the processing

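The tests with 1 summit per region and the exchange test were chosen after seeing the data. No paired analysis was possible because there was 1 group. The strongest 10688 peaks of the pooled list were identical to the IDR list, so that alternative tests nothing. Promoter excess, density on X and 4, both Maf motifs and the signal difference kept direction and side of the threshold in every other alternative run, apart from those below, whose cause was not tested. Concordance was 62.7% with summits within 50 bp, 89.1% with any overlap, 71.3% with 50% reciprocal overlap and 72.8% with all peaks. The share of IDR peaks matched in all 3 replicates was 51.7%, 83.6%, 55.8% and 96.0% under the same settings, 39.5% when all IDR peaks were matched to only the strongest 5344 summits of each replicate, which caps the share by construction, and 81.9% to 83.2% for matches in both remaining replicates when 1 was left out, which is less strict by construction. Somatic exceeded germline piRNA genes at 2000 bp (odds ratio 5, Fisher's exact p = 0.0359, against 0.0605 to 0.287 in the other settings). The TGCTGAC ratio was 1.80 at summits within 500 bp of a TSS, no longer past the exact sign test (p = 0.789), and that of the full site with at most 1 mismatch was 4 (p = 0.0987). The exchange test called 6 other motifs above their flanks, against 2 by the sign test. From 6 to 12 gene lists passed, against 9, and 5 to 9 of the same lists passed in the same direction. Among values for single lists, 23 passed and 23 missed the threshold only under the alternative, and 3 reversed: Notch genes without replicate 3 (odds ratio 0.962, and 0.962 to 1.51 with each replicate left out in turn) and germline piRNA genes at 2000 bp (0.991) and against matched genes (observed over expected 0.974). None of those 3 passed a test. Ribosomal protein, bZIP, basement membrane and histone lists passed in all 10 other alternatives. Unknown depth limits what the weaker peaks can show.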

Other observations

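The genes and classes named in this paragraph and the next were chosen after the data were seen. So was the bootstrap interval for the promoter ratio further on, added when that ratio was known. The full Maf site here is the palindromic site with at most 2 mismatches. The strongest peaks with it lay in introns of shn, Vha100-2 and CHES-1-like (X, 7703259 to 7704092). Next were the promoters of alc (2R, 9137172 to 9137901) and Cmpk (3R, 26054965 to 26055584). An intron of ex (2L, 435104 to 436249), the gene of a Hippo pathway component, followed. CG5946, RpS5b, Tsp74F, sea and CtsB had such a peak at the promoter, and Men-b had one in an intron. The peaks at alc, Cmpk, ex, Men-b, Tsp74F and CtsB did not hold the exact core TGCTGAC, so their sites are inexact matches.

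Genes of tRNAs had a summit within 1000 bp of a TSS in 100 of 290 cases (34.5%, 95% Wilson interval 29.2 to 40.1%). So did snoRNA genes in 79 of 269 (29.4%), snRNA genes in 8 of 32 (25%) and rRNA genes in 0 of 99. Genes annotated only as non-coding RNA had one in 623 of 3261 (19.1%) and pseudogenes in 20 of 268 (7.46%). Protein-coding genes had one in 36.4%. Annotated transposable elements held 21 summits (0.196%), against 5.82% of summits in 100 shuffles, which ranged from 5.17% to 6.30%. Mappability was not accounted for in these shares or in the shuffles, so low values cannot be assigned to Traffic jam. Among 7-mers, those ranked after TGCTGAC by summit to flank ratio included ACTATCG (2.48) and CTATCGA (2.28), which share TATCG with the replication-related element, and CGTCAGC (2.39), which shares GTCAGC with the Maf core.

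TGCTGAC was rarer at promoter peaks than at other peaks. The summit to flank ratio at promoters was 1.80 (95% bootstrap interval 1.53 to 2.11), above the bound of 1.5 set in advance. The core was thus enriched over the flanks at promoter summits. This does not show that any promoter peak depends on the core. Over all summits, other sequences also passed 1.5, such as the GAGA factor site (1.88). The bound of 1.5 was also too narrow. Signal independent of the core at only part of the promoters would give any ratio between 1 and the 3.70 of other peaks, so this explanation stays open. The replication-related element (16.7 times) and Motif 1 (73.3 times as frequent at promoter peaks) cannot decide it. Sequences common at promoters would be frequent at these peaks with or without it, since the peaks were grouped by distance to a TSS. Weak promoter peaks near the list's threshold stay open too: in the strongest of the 5 signal groups, 11.1% of promoter peaks and 13.2% of other peaks held the core, a ratio of 0.840 (Fisher's exact p = 0.144). No biological explanation was tested, since there was 1 group.

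More summits per Mb were found on X. A higher density of TSSs on X could give this, but X had 166.0 TSSs per Mb against 178.3 on the other arms, and summits per TSS were 1.28 times as frequent on X (exact binomial p = 6.30e-23). Several summits in 1 region do not account for all of it. Distinct regions had a density on X 1.12 times that given by its length (exact binomial p = 1.21e-07), against 1.15 times for summits. A promoter summit was present at 42.1% of X-linked coding genes and 35.3% of others (Fisher's exact p = 1.49e-09). Differences in accessibility and mappability between chromosomes were not tested, and no biological explanation was tested.

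The summits downstream of tj were stronger than the one at its promoter, with a ratio of the strongest downstream summit to the promoter summit of 6.01 ± 2.09 (SD, n = 3), and 8.38, 5.20 and 4.45 in replicates 1, 2 and 3. Whether the tagged line carries extra copies of the locus is not given in the sources used here, so whether they account for any of this is open. Of 2 tests of extra copies that were tried, the first assumed a copy gain and the other restated the ratio itself, so neither is used.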
